A study of Mus musculus with 11 samples.

How the data were processed

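Ribosome footprints were measured in livers of male wild-type mice fed chow or a high-fat, high-sugar (HFHS) diet. A footprint is the stretch of mRNA that a ribosome protects from RNase I. Per the labels' protocols, 200 mg of frozen liver was lysed and digested, 10 µg of RNA was run on a gel, and fragments of about 30 nt (monosomes, single ribosomes) or 60 nt (disomes, a pair of ribosomes packed against each other) were excised. Also per the labels' protocols, each sample received a 3' adaptor that carried a sample barcode and a unique molecular identifier of 8 nt, and samples were pooled before ribosomal RNA was depleted. The submitters' processing notes name cutadapt 3.5 and Bowtie2. How the molecular identifiers entered the counting, the genome build, the annotation, the strand setting and the treatment of reads shared between gene copies are not given in the sources used here.

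The table deposited by the authors holds raw counts of footprints, as whole numbers that were not normalized, for 22019 genes in 11 libraries. Each line carries an Ensembl gene identifier and 1 Ensembl transcript identifier. Of these lines, 8319 were 0 in every library. The column names gave the footprint class, the diet and the sample barcode, but no replicate number, so each column was placed in its group and named here by its barcode. Replicate 2 of the HFHS disome group was not analysed here. The files do not pair gene identifiers with gene names: 0 of the identifiers matched the RefSeq gene table used here (assembly GRCm38.p6, 49997 genes). Genes are therefore given by identifier, and no coordinate or sequence is given. For the same reason 30 gene lists that had been fixed (lipid, bile acid, stress response, ribosome quality control and cell type lists among them), the kinase ZAK, the shares of counts of named gene families, and checks against coding length were not analysed here.

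Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM normalization, and the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Genes below the threshold are called changed. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. There were 5 comparisons: HFHS against chow in monosomes, the same in disomes, the difference of these diet effects in 1 model over all 11 libraries, and disomes against monosomes within chow and within HFHS. Levels are in CPM (edgeR's scaled counts) after TMM within the fit, as mean ± SD. Library totals carry no absolute amount, so every change is relative to the average gene of its fit. The 5 comparisons with their tests, the tests of shares, the alternatives and the rule for named genes were fixed before the data were examined. That rule took adjusted p below 0.05, libraries of the groups not overlapping, and at least 10 CPM in 1 group, ranked by log2 fold change. It takes up to 10 genes in each direction, and because they are unnamed the first 2 in each direction are printed. The fixed rule also passes over predicted genes and pseudogenes and asks for a remark on families whose copies share reads. Without gene names these parts could not be applied, so such genes may be among those printed. For the difference of diet effects, where fewer than 5 genes passed, the 5 with the smallest p are named as not passing, and 2 in each direction are printed.

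Agreement between comparisons was described by the share of called genes with the same sign, with an exact 95% binomial interval, by the overlap expected of independent lists, and by limma's rotation test fry (limma 3.58.1) with the called genes weighted by their sign. These descriptions were added after the files were read. A grouping of genes by abundance against the disome-to-monosome ratio was also run and is not reported, because the count filter keeps genes of low monosome level only where their disome level is high. The share of counts taken by the 10 most abundant genes was compared with exact permutation tests. Total counts were 1248781 (ATCGT), 795145 (AGCTA) and 1025379 (CGTAA) in chow monosomes and 1383868 (CTAGA), 1196240 (GATCA) and 1612324 (GCATA) in HFHS monosomes. They were 147212 (AGCTA), 245011 (ATCGT) and 279331 (CGTAA) in chow disomes and 235748 (CTAGA) and 238837 (GCATA) in HFHS disomes. In a single library 3 counts corresponded to 1.86 to 3.77 CPM in monosomes and 10.7 to 20.4 CPM in disomes. A gene with no count in any library of a group was given a floor of 3 counts over that group. Floors cover counting error only. The binomial intervals treat genes as independent trials and the bootstrap interval resamples genes, so none of these covers variation between samples. The labels give the samples as separate replicates without saying that each came from a separate animal, so p-values measure the spread between these samples. edgeR pools its estimate of this spread across genes, so a p-value does not rest on the spread of its own gene alone. No replicate pair of a group agreed within counting noise, with a chi-square per degree of freedom between 1.87 and 9.20.

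Each fit was tested on simulated counts with 200 changed genes, 50 at each fold. At 2-fold, 58% of the changed genes were recovered for the diet in monosomes, 54% for the diet in disomes, 4% for the difference of diet effects, 52% for disomes against monosomes in chow and 26% in HFHS. At 4-fold the recovered shares were 88%, 94%, 36%, 86% and 60% in the same order, and at 8-fold 88%, 96%, 74%, 94% and 84%. False calls were between 1.50% and 6.52% of calls. The simulation gave each unchanged gene the same mean level in all libraries of a fit and drew counts independently. The real fit of disomes against monosomes in chow called 2114 genes, far more than the 200 changed here. These rates may therefore not carry over to the real data, above all where footprint classes are compared. Larger folds were added to this simulation after its first run had recovered no 2-fold change in the difference of diet effects. The alternatives were DESeq2 1.42.0, its size factors (RLE) within edgeR, no filter, a minimum count of 50, the test without robust estimation, 1 fit over all libraries, TMM within each footprint class, and each library left out in turn. Added after the data were seen were the removal of the 20 most abundant genes alone (the fixed version also removed the Mup genes, which could not be identified), the sample barcode as a block, and the removal of both chow libraries with barcode AGCTA. Figures were drawn with matplotlib 3.10.9.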

Results

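The study compared where and how often ribosomes collided in liver on 2 diets, under a title that concerns translation impairment by reactive oxygen species and the kinase ZAK, which responds to stalled ribosomes. Monosome footprints measure how many ribosomes occupy a coding sequence. Disome footprints measure how many ribosomes are packed directly behind another. The monosome libraries comprised 3 chow and 3 HFHS samples, and the disome libraries comprised 3 chow and 2 HFHS samples. Total counts ran from 795145 to 1248781 in chow monosomes and from 1196240 to 1612324 in HFHS monosomes. Disome libraries were shallower, with 147212 to 279331 counts in chow and 235748 to 238837 in HFHS. Between 5607 and 7357 genes reached 10 counts in a monosome library, against 1793 to 3145 in a disome library.

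The same gene, ENSMUSG00000029368, was the most abundant in all 11 libraries. It took 8.81% ± 0.48 of counts in chow monosomes and 3.23% ± 0.057 in chow disomes (SD, n = 3 each). The 10 most abundant genes took 21.8% ± 0.96 of chow monosome counts (n = 3), 22.5% ± 0.23 of HFHS monosome counts (n = 3), 15.9% ± 0.13 of chow disome counts (n = 3) and 16.5% ± 0.58 of HFHS disome counts (n = 2). The diets differed by 0.711 percentage points in monosomes (exact permutation p = 0.2, two-sided) and by 0.657 points in disomes (exact permutation p = 0.1). Relative to monosomes, the share in disomes differed by -5.91 points in chow and by -5.96 points in HFHS (exact permutation p = 0.1 for each). The smallest p that these group sizes allow is 0.1. The diet difference in monosomes was 0.160 points without the chow library AGCTA, and that in disomes was 0.245 points without the HFHS library CTAGA and 1.07 points without GCATA.

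In both footprint classes, the chow libraries with barcode AGCTA stood apart from the other chow libraries. Genes with a mean above 50 CPM over all libraries were used for correlations of log2(CPM + 1). The monosome library AGCTA correlated with the others of its group at r = 0.82 and 0.83, while those correlated at r = 0.98 with each other. In disomes the corresponding values were r = 0.79, 0.79 and 0.96. Genes high in AGCTA alone can enter this selection, so the low r does not show that the rest of the library differs. In the monosome library AGCTA, 30 genes lay above 20 CPM and more than 8 times above the highest other monosome library plus 1 CPM, a rule chosen after the values were seen. These genes took 4.15% of its counts, against at most 0.038% in any other monosome library. All 30 also stood apart in the disome library of this barcode, where they took 3.97% of counts, against at most 0.016% elsewhere. Of the 30, 8 passed the filter for the diet in monosomes, with a median log2 fold change of -6.06, and none of them was called (smallest adjusted p = 0.435). For the diet in disomes and for disomes against monosomes in chow, 1 of the 30 was tested, and it was called in neither.

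**Figure D1:**
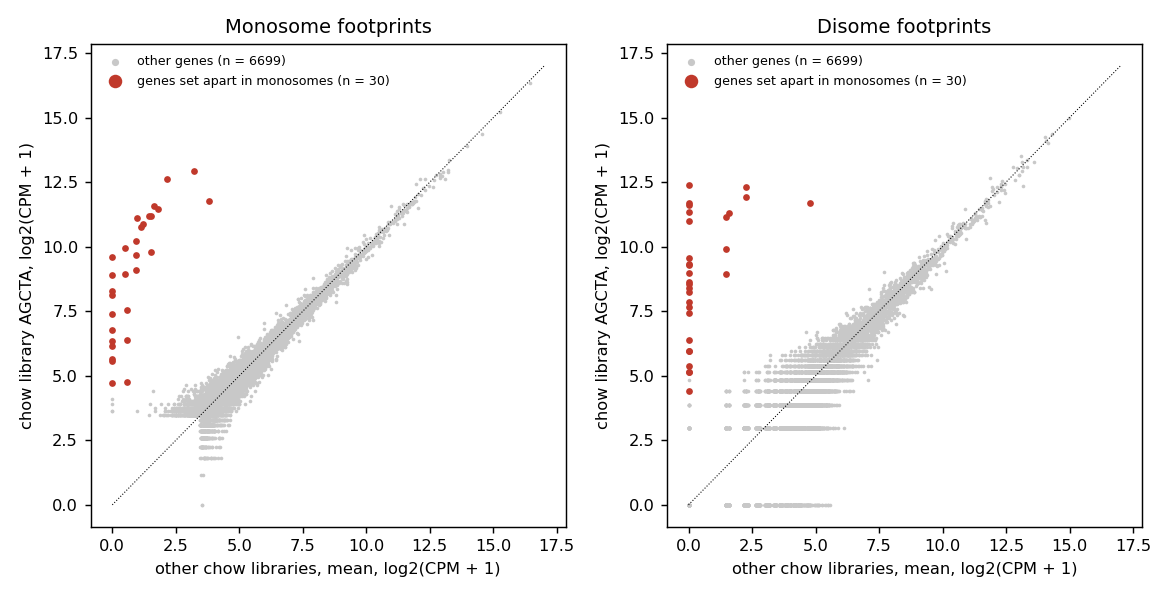
Level of each gene in the chow library with barcode AGCTA (vertical axis) against the mean of the other chow libraries (horizontal axis), both as log2(CPM + 1), for monosomes (left) and disomes (right). Each point is a gene, the dotted line marks equal levels, and the 30 red genes set apart in monosomes lie above the line in both panels.

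The first comparison asked which genes changed their monosome footprint level with the HFHS diet. The libraries analysed here hold no measure of mRNA. A change in mRNA level can therefore not be told from a change in ribosomes per mRNA. ENSMUSG00000032080 rose most in monosome footprints, from 230.5 ± 32.7 CPM in chow to 2854 ± 1062 CPM in HFHS (n = 3 each), a log2 fold change of 3.63 ± 0.32 (SE) with edgeR adjusted p = 0.00359. ENSMUSG00000061780 rose from 4.57 ± 5.02 to 41.8 ± 10.8 CPM, a log2 fold change of 3.35 ± 0.41 (adjusted p = 3.2e-05). ENSMUSG00000090877 fell from 22.4 ± 10.8 to 4.00 ± 3.34 CPM, a log2 fold change of -2.48 ± 0.46 (adjusted p = 0.00207). ENSMUSG00000041293 fell from 12.3 ± 1.97 to 2.07 ± 1.57 CPM, a log2 fold change of -2.44 ± 0.49 (adjusted p = 0.00222). The lower group of the last 3 genes held few counts, so the sizes of their changes are uncertain. These were 3, 8 and 1 in chow for ENSMUSG00000061780. In HFHS they were 4, 9 and 2 for ENSMUSG00000090877 and 2, 1 and 6 for ENSMUSG00000041293. In total, 204 genes were higher and 110 lower in HFHS among 6754 tested. Of these, 58 rose and 42 fell by more than 2-fold, and the called genes had a median log2 change of 0.75 upward and -0.82 downward.

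Single libraries moved these results. The number higher was 131 without the chow library AGCTA and 85 without the chow library CGTAA. The number lower was 57 without CGTAA, 68 without the HFHS library CTAGA and 62 without the HFHS library GATCA. The change of ENSMUSG00000032080 kept its size but missed the threshold without the chow library ATCGT (adjusted p = 0.0556) or without CGTAA (adjusted p = 0.0531). The log2 fold change of ENSMUSG00000061780 was 4.48 without AGCTA, that of ENSMUSG00000090877 was -3.29 without GATCA, and that of ENSMUSG00000041293 was -3.25 without the HFHS library GCATA, all past the threshold. DESeq2 called 56 genes lower, and a minimum count of 50 left 125 genes higher.

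The second comparison asked the same of disome footprints. ENSMUSG00000032080 was again the gene that rose most, from 69.9 ± 27.4 CPM in chow (n = 3) to 596 ± 155 CPM in HFHS (n = 2), a log2 fold change of 3.19 ± 0.24 (adjusted p = 9.23e-37). That adjusted p depends on how the spread is pooled across genes. It was 3.7e-15 without robust estimation, 2.17e-14 with DESeq2 and 0.00882 with all 11 libraries in 1 edgeR fit. ENSMUSG00000022615 rose from 12.3 ± 4.17 to 90.5 ± 16.4 CPM, a log2 fold change of 2.91 ± 0.56 (adjusted p = 3.34e-05). ENSMUSG00000090175 fell from 74.2 ± 38.4 to 11.6 ± 3.28 CPM, a log2 fold change of -2.64 ± 0.58 (adjusted p = 0.000654). ENSMUSG00000042834 fell from 79.95 ± 33.1 to 13.9 ± 13.1 CPM, a log2 fold change of -2.55 ± 0.53 (adjusted p = 0.000184). The lower group of each of these genes except ENSMUSG00000032080 held few disome counts. They were 2, 3 and 2 in chow for ENSMUSG00000022615. In HFHS they were 2 and 3 for ENSMUSG00000090175 and 5 and 1 for ENSMUSG00000042834. The sizes of these changes are therefore uncertain. In total, 51 genes were higher and 32 lower among 2804 tested, a smaller set than in monosomes because fewer genes reached the count filter.

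These counts rested on few libraries. The number higher was 25 without the chow library AGCTA, 32 without ATCGT, 23 without CGTAA, 31 without the HFHS library CTAGA and 20 without GCATA. The number lower was 18 without ATCGT, 18 without CGTAA and 20 without GCATA. Of the genes named, ENSMUSG00000090175 missed the threshold without ATCGT (log2 fold change -2.09, adjusted p = 0.311), ENSMUSG00000042834 without CGTAA (log2 fold change -2.07, adjusted p = 0.275) and without GCATA (log2 fold change -1.81, adjusted p = 0.16), and ENSMUSG00000022615 without CTAGA (log2 fold change 2.72, adjusted p = 0.172). Without CTAGA the log2 fold change of ENSMUSG00000042834 was -3.99 and past the threshold, on 1 count in the HFHS library left. DESeq2 called 16 genes higher and 10 lower. The number lower was 21 with no filter and 21 when all 11 libraries were fitted together.

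**Figure D2:**
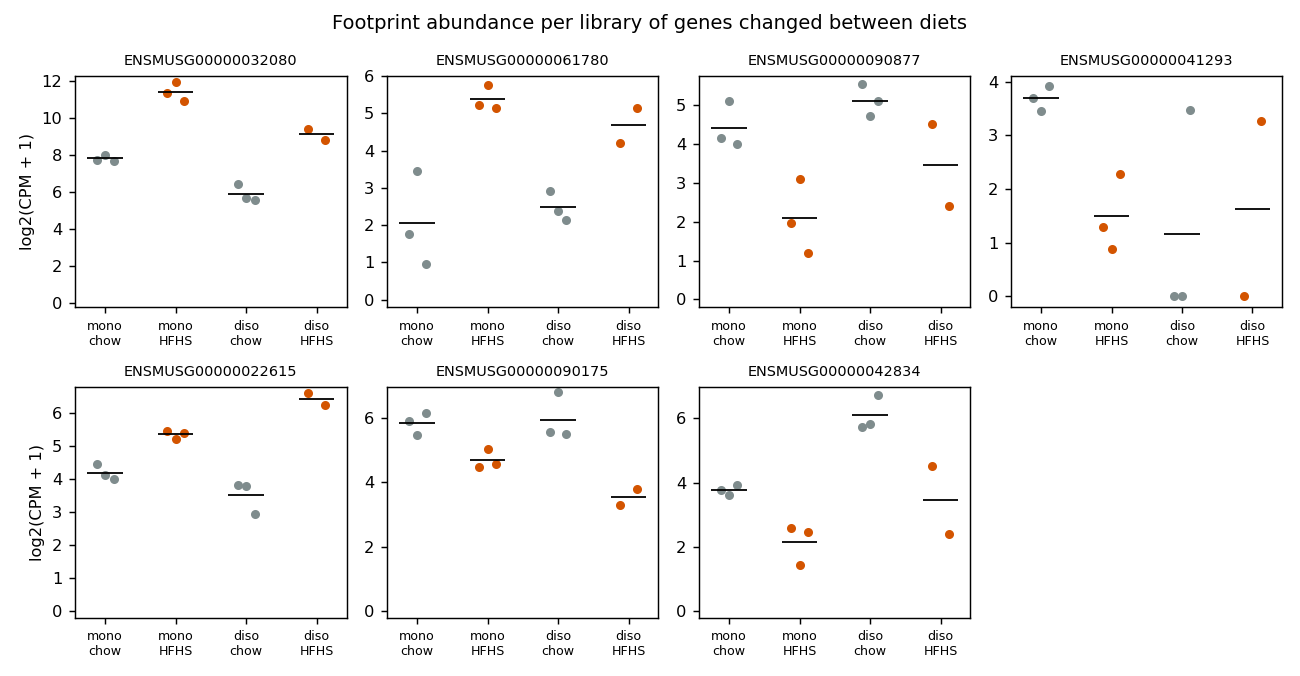
Footprint level, as log2(CPM + 1) after TMM within each footprint class, of the 7 genes named in the diet comparisons. Each point is a library (chow grey, HFHS orange) and each bar the group mean of 3 libraries, or 2 for HFHS disomes. ENSMUSG00000032080 was higher in every HFHS library than in any chow library of the same class.

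The diet effects in the footprint classes were then set against each other. Of 230 genes called in monosomes that were also tested in disomes, 220 moved in the same direction in disomes (95.7%, exact 95% interval 92.1 to 97.9). Their log2 fold changes in the 2 classes correlated at Pearson r = 0.87. Over all 2788 genes tested in both classes the correlation was weaker (Pearson r = 0.59, Spearman 0.49). In both classes 39 genes were called higher and 20 lower, and 0 were called in opposite directions. Independent lists would share 3.02 genes higher and 0.723 lower. For the genes called higher in monosomes, the median log2 fold change was 0.67 in monosomes and 0.56 in disomes. For the genes called lower it was -0.71 in monosomes and -0.73 in disomes. Monosome calls moved together in disomes in the rotation test (adjusted p over 3 tests = 0.00208), and disome calls moved together in monosomes (adjusted p = 0.000119). No library entered both fits. Libraries of the same barcode deviated from their group means together in the 2 classes, although the labels do not tie a barcode to an animal. This concordance can therefore not be taken as one between independent animals. The overlap given for independent lists does not allow for such shared deviations.

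**Figure D3:**
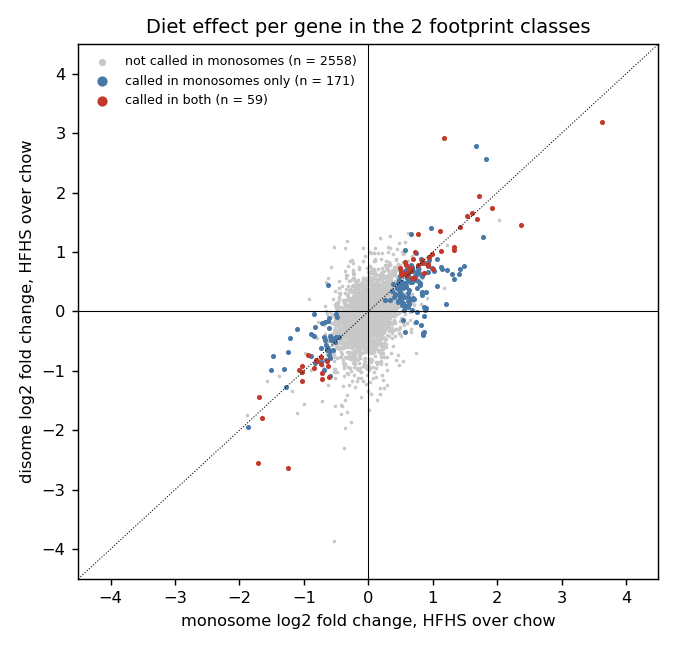
Log2 fold change, HFHS over chow, in monosome footprints (horizontal axis) and disome footprints (vertical axis) for the 2788 genes tested in both classes. Each point is a gene, and the dotted line marks equal change. The genes called in both classes (39 higher, 20 lower) lie to the lower left and upper right of the origin.

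The third comparison tested whether disome footprints of single genes responded to diet differently from their monosome footprints. It asked whether collisions changed beyond the monosome level, relative to the average gene. Normalization over all 11 libraries removes a change in disomes common to all genes, so such a change could not be seen. No gene passed the threshold among 7236 tested with edgeR, with 358 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.763. Those 358 are no more than a threshold of 0.05 gives by chance. DESeq2 called 0 genes as well, with 196 at an unadjusted p below 0.05. In the simulation for this comparison, 4% of 2-fold, 36% of 4-fold and 74% of 8-fold differences were recovered, so the absence of calls does not exclude differences of these sizes. Among the 5 genes with the smallest p, which did not pass, the difference of diet effects was 3.06 ± 0.80 (log2) for ENSMUSG00000062014 and 1.52 ± 0.43 for ENSMUSG00000007836. It was -1.14 ± 0.30 for ENSMUSG00000064345 and -4.32 ± 1.16 for ENSMUSG00000021336. The last value rested on 1 count in the HFHS disome libraries, which lay in CTAGA: it was -3.42 without GCATA. Without CTAGA no count was left, and the fitted value of -8.11 is not a measured size. The value of ENSMUSG00000062014 rested on chow disome counts of 1, 2 and 3. When the sample barcode was used as a block, an alternative chosen after the data were seen, 7 genes were lower and 0 higher, ENSMUSG00000064345 among them (adjusted p = 0.0159).

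The fourth comparison described which genes carried more or fewer disomes than their monosome level in chow. ENSMUSG00000090353 had the highest ratio, with 57.6 ± 20.9 CPM in disomes and 0.987 ± 1.05 CPM in monosomes (n = 3 each), a log2 ratio of 5.50 ± 0.53 (adjusted p = 6.76e-11). Its monosome counts were 1, 0 and 2, at the floor, so the size of this ratio is uncertain. The count filter keeps genes of such low monosome level only where their disome level is high, which bears on the highest ratios. ENSMUSG00000024163 followed with 72.4 ± 24.7 CPM in disomes and 4.66 ± 1.42 CPM in monosomes, a log2 ratio of 3.81 ± 0.41 (adjusted p = 7.41e-10). ENSMUSG00000074129 had no disome count in chow and 49.4 ± 13.5 CPM in monosomes, so that it was at least 10.8-fold lower in disomes (adjusted p = 3.78e-07). ENSMUSG00000056116 had no disome count in chow and 30.0 ± 5.73 CPM in monosomes, at least 6.57-fold lower (adjusted p = 1.17e-05). In total, 1017 genes were higher and 1097 lower in disomes among 4713 tested, which is 44.9% of them, and 602 and 769 differed by more than 2-fold. Without the filter the counts were 889 higher and 1532 lower, and the median of the genes shared with the filtered fit shifted by -0.17 on the log2 scale. With a minimum count of 50 they were 412 and 486. Without the chow monosome library CGTAA, the log2 ratio of ENSMUSG00000090353 was 6.16.

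The fifth comparison gave the same ratio in HFHS livers. ENSMUSG00000090353 again had the highest ratio, with 70.7 ± 59.4 CPM in disomes (n = 2) and 1.51 ± 2.62 CPM in monosomes (n = 3), a log2 ratio of 5.44 ± 1.00 (adjusted p = 0.00594). DESeq2 gave it an adjusted p of 0.0783, and its log2 ratio was 4.81 without the monosome library GCATA and 6.11 without the disome library GCATA. All 6 of its monosome counts lay in the library CTAGA. Without that library, its mean disome level was 63.3 times a floor of 3 monosome counts. The disome library CTAGA, of the same barcode, stayed in that mean with 28 counts, against 7 in the disome library GCATA. The value of 63.3 is therefore not a lower bound. ENSMUSG00000090272 had 18.3 ± 2.63 CPM in disomes and 1.56 ± 0.95 CPM in monosomes, a log2 ratio of 3.49 ± 0.75 (adjusted p = 0.000794). Its monosome counts were 1, 3 and 2, so the size of this ratio is uncertain as well. ENSMUSG00000048376 had no disome count in HFHS and 37.9 ± 6.68 CPM in monosomes, at least 6.22-fold lower in disomes (adjusted p = 6.67e-05). ENSMUSG00000068240 had no disome count in HFHS and 35.3 ± 15.2 CPM in monosomes, at least 5.80-fold lower (adjusted p = 0.00319, and 0.05 without the disome library GCATA, just above the threshold). In total, 854 genes were higher and 1010 lower among 7437 tested. The filter scales its minimum count to the median library size and asks for it in as many libraries as the smallest group. Both differ between the diets. The numbers tested, 7437 here and 4713 in chow, and the numbers called therefore do not compare the diets. The counts were 425 and 555 without the disome library CTAGA, and 461 and 613 without GCATA. DESeq2 called 611 genes lower. Without the filter 671 genes were higher and 1218 lower, with a median shift of -0.14 on the log2 scale.

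Relative to the average gene, most genes called in chow kept the direction of their disome-to-monosome ratio in HFHS. Normalization within each diet removes any rise or fall of disomes common to all genes, so such a change cannot be seen. A shared sign also does not show that the sizes of the ratios were equal. Of 2104 genes called in chow and tested in HFHS, 2052 had the same sign in HFHS (97.5%, exact 95% interval 96.8 to 98.1). In both diets 578 genes were called higher and 707 lower, and 0 were called in opposite directions, where independent lists would share 148 and 202. The genes called in chow moved together in HFHS in the rotation test (adjusted p = 0.000119). Disome and monosome libraries came from separately named pools, so the ratio holds any difference between pools as well as between footprint classes. The diets share this difference, which the same-sign share then includes.

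**Figure D4:**
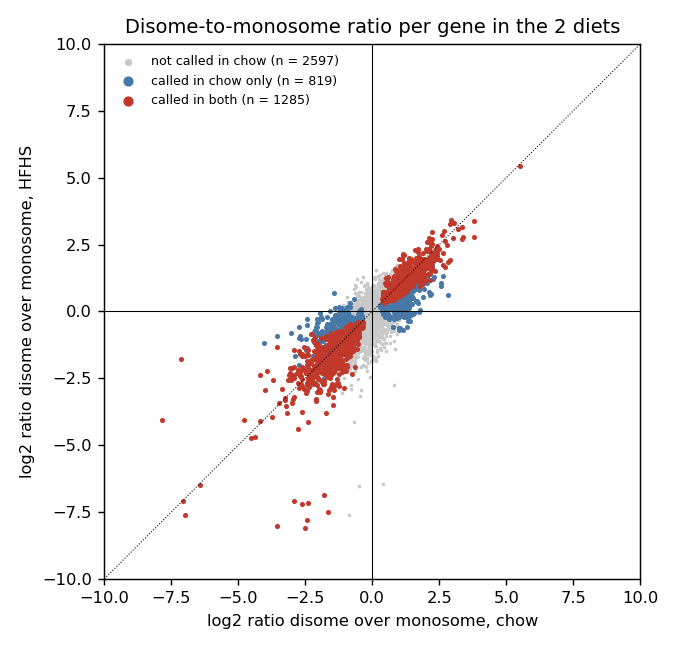
Log2 ratio of disome over monosome footprints in chow (horizontal axis) and HFHS (vertical axis) for the 4701 genes tested in both diets. Each point is a gene and the dotted line marks equal ratios. The genes called in both diets (578 higher, 707 lower) have the same sign in both, and the points far below the line include genes with no disome count, whose fitted ratios are not bounds.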

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

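The shuffles, the rotation tests, the removal of the AGCTA libraries and the count of shared barcodes were tests chosen after the result was seen, and the run of genes itself was picked for its values. With the sample barcode as a block, 7 genes had a lower diet effect in disome than in monosome footprints. All 7 belonged to a run of 12 tested genes with neighbouring Ensembl identifiers that includes ENSMUSG00000064345. The run lies within ENSMUSG00000064341 to ENSMUSG00000064370. Without gene names, whether its genes share an origin or a function was not tested. The 7 calls are singled out because a test of the difference between the footprint classes passed its threshold in the fit with the block. The fit without the block called none of them. All 12 genes lay below 0 in it, with a median of -1.02 on the log2 scale. Their median diet effect was 0.78 in monosomes, where 6 were called higher, and -0.23 in disomes for the 11 tested there (rotation test, adjusted p over 5 comparisons = 0.0967 and 0.687). Of the 12, 10 were lower in disomes than in monosomes in HFHS (adjusted p of the set = 0.0967), and in chow 2 were higher and 1 lower (0.802). As a set, the 12 did not pass the rotation test for the difference, which keeps the correlation between genes (adjusted p = 0.102), so variation between samples that these genes share stays open. With the barcode block, a version added after that, the set did not pass either (limma's fry, adjusted p over 2 fits = 0.144, and 0.144 without both AGCTA libraries), with 3 and 2 residual degrees of freedom left. The run took 0.239% ± 0.031 of chow monosome counts, 0.395% ± 0.060 of HFHS monosome counts, 0.261% ± 0.081 of chow disome counts (SD, n = 3 each) and 0.224% ± 0.0089 of HFHS disome counts (n = 2).

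Because of that choice, 0 of 10000 random sets matched on disome count and 0 of 7202 other runs of consecutive tested identifiers having as low a median decides nothing about counting noise or a chance run. Allowing for the choice, 166 of 1000 shuffles of the fold changes held a run as low somewhere, which does not exclude counting noise. Those shuffled runs had a median disome count of 3.3, against 33.7 in the observed run, and when fold changes were scaled by their standard errors, a version added after the first shuffle was seen, 0 of 1000 shuffles reached the observed value. Shuffling breaks any variation that neighbouring genes share across libraries, so this result speaks only about noise independent between genes. Without both AGCTA libraries the median was -1.23. From monosomes to disomes, the run's share of counts fell in AGCTA from 0.274% to 0.183%. It also fell in the HFHS barcodes found in both classes (CTAGA 0.463% to 0.231%, GCATA 0.359% to 0.218%). In chow it rose in ATCGT (0.230% to 0.346%) and CGTAA (0.214% to 0.254%). AGCTA thus lay against the pattern, so leaving it out could not show whether another single chow sample carries it. Whether there is a difference at all therefore stays open. If there is one, an effect of the diet and of the sample barcodes, of which 0 were used in both diets, cannot be told apart.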

How the results depend on the processing

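The removal of abundant genes without the Mup genes, the sample barcode as a block and the removal of both AGCTA libraries were chosen after the data were seen. No paired analysis was possible by the labels' pairs because the table's columns carry no replicate numbers. The barcode block paired libraries by their adaptor instead, which the labels do not tie to an animal. Not run for want of gene names were the removal of the Mup genes and every alternative for gene lists. Of 256 values of the named genes under alternatives, 246 kept their direction and their side of the threshold, 8 kept the direction and missed it, 2 passed it newly, and none turned; values fitted on a group left with no count are among them. A further 40 had no value: in 33 the gene was not among those tested (16 of these at a minimum count of 50), and in 7 DESeq2's independent filter gave no adjusted p, 6 of them among the 8 named diet results. For counts and shares, the cause of the changes given here was not tested, except that a stricter filter tests fewer genes and a left-out library leaves fewer samples. DESeq2 called 56 genes lower for the diet in monosomes, 16 higher and 10 lower in disomes, and 611 lower for disomes against monosomes in HFHS. A minimum count of 50 gave 125 higher for the diet in monosomes and 412 higher and 486 lower for disomes against monosomes in chow. For the diet in disomes, 21 genes were lower with no filter and 21 with all 11 libraries in 1 fit.

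With 1 library left out, the diet in monosomes gave 85 to 203 genes higher and 57 to 117 lower, and in disomes 20 to 32 and 18 to 26. Disomes against monosomes in HFHS gave 425 to 825 higher and 555 to 861 lower. A group left with 1 library was assumed to vary like the others. The same-sign share of monosome diet calls in disomes was 88.4% to 95.6% with 1 library left out and 91.1% with no filter. The share of chow ratio calls in HFHS was 94.7% to 98.5% with 1 library left out, 99.1% with DESeq2, 99.3% at a minimum count of 50 and 98.4% without both AGCTA libraries.

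The barcode block called 7 genes lower for the difference of diet effects, and 8 without both AGCTA libraries, where every other alternative called 0. For disomes against monosomes it called 1145 genes higher and 1191 lower in chow, and 945 and 1089 in HFHS. In chow, each library's deviation from its group mean correlated best with that of its own barcode in the other class, also without the 30 genes set apart (r = 0.32, 0.27 and 0.29), a hint from the data, not the design. In HFHS only 2 barcodes were shared, with r = 0.45.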

Other observations

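The tests of the share of counts held by thinned libraries and of a difference limited to 1 footprint class were chosen after the result was seen. The chow libraries with barcode AGCTA held 30 genes far above the level of any other library. Lower depth may add such genes in disomes, where another library thinned to the same total held up to 11 of them, but not their weight: those genes took at most 0.0238% of the thinned counts. The difference was not limited to 1 footprint class, since 100% of the genes set apart in monosomes were set apart in disomes of the same barcode. A candidate explanation is RNA of another source mixed into a liver sample before the footprint classes were separated. This takes both AGCTA libraries as the same sample, which the labels do not state. Such mixing adds transcripts and lowers no single gene. Its test took 700 abundant genes and left out the 30. Over the 700, the lower tail of log2 ratios to the other chow libraries was 0.828 times that between those libraries. The 95% bootstrap interval was 0.736 to 0.929, and the upper tail was 0.987 times. Any cause limited to the 30 genes leaves ordinary tails as well, so these values cannot tell mixing from a difference of the liver tissue itself. A difference of the liver tissue stays open, untested, and without gene names no source was tested.

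With 3 libraries against 3 there are 10 splits of the samples, so a share under 0.05 cannot be reached. For the diet in monosomes, 1 of the 10 splits, the real one, gave as many as 314 genes, and the highest of the others gave 0. For disomes against monosomes in chow, 1 of the 10 splits gave as many as 2114 genes, and the highest of the others gave 0.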
